A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

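Each of 2 two-colour tiling arrays was hybridised with nucleosomal DNA in Cy5 and genomic DNA in Cy3, per the labels, in the same dye orientation, so a dye bias is not removed by averaging. DNA had been amplified linearly before labelling, per the labels' protocols. The deposited scanner files give spot intensity on a linear scale: raw mean and local background intensity of each channel, and a processed intensity that, per the file headers, Agilent Feature Extraction 9.1.3.1 made by background subtraction, detrending over the slide and scaling each channel by 1 dye factor. Each deposited scanner file also gives a log10 ratio of processed Cy5 over Cy3, per the file headers, which was read but not used for results. A deposited value table of the same arrays holds log2 values. Set against the scanner values, they equalled log2 of processed Cy5 over processed Cy3, with no centring, to within 5.00e-06, and had medians of -0.13 and -0.13. The direction is therefore the same in all files. The table was used as an alternative.

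The arrays held 45219 spots, of which 3444 were controls. From the processed intensities log2 ratios of Cy5 over Cy3 were computed for the 41775 other probes, which were 45 to 60 bases long, and each array was centred on its median, with no loess and no quantile scaling, since most probes of such an array carry signal. Before centring the medians were -0.13 on both arrays. Probes were left out where a spot was flagged as non-uniform (174) or where Cy3 was not well above background on an array (147), which left 41454. Saturated spots stayed: 4.38% and 4.59% of probes were saturated in Cy5 on replicates 1 and 2, and 1573 kept probes on both. Their ratios are lower bounds where Cy3 was not saturated as well. Cy3 was saturated on both arrays at 156 kept probes. A control probe spotted 312 times had an SD of 0.064 and 0.080 (log2) within the arrays. The arrays lay on 1 slide and were scanned together, so neither slide nor scan could be tested as a batch.

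The genome build of the probe coordinates is not given in the sources used here, and no genome was used. Coordinates are those of the array's own annotation, counted from 1. Regions were taken from that annotation (inside genes, upstream, between divergent genes, downstream). Gene names were updated through a table of yeast genes on assembly R64, used only for names, strand and gene order: 5664 of 5688 names matched, 123 of them received a newer symbol, and 24 were kept as on the array. The side of the upstream probes matched the strand in the systematic name for 5008 genes and did not for 1. Start and stop codons were placed midway between the flanking probes. Intergenic stretches that hold a tRNA gene (212) or a small nuclear or nucleolar RNA gene (67) were found by gene order.

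Probes, and the mean per gene of upstream probes (within 500 bp) and of coding probes, were tested against 0 with limma 3.58.1 (lmFit on an intercept, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of upstream and coding means per gene was tested in the same way. Only 1 residual degree of freedom is left for each probe, and the spread is moderated across probes. Region classes were compared by medians with a two-sided permutation test of 10000 circular shifts of the values along each chromosome (1000 in alternatives), adjusted over the special regions. This test describes these arrays. Gene lists were tested with camera (preset correlation 0.01, and an estimated one) over 30 tests. The lists, fixed before the data were examined, were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, pheromone response and a-specific genes, G1/S, G2/M, histones, glycolysis and fermentation, phosphate response, galactose use, chaperones and heat shock, meiosis and sporulation, subtelomeric families, RNA polymerase II and general factors, and proteasome. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

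The genes named were chosen by a rule fixed at the same time. For upstream and coding regions apart, it takes the 8 lowest and 8 highest genes past the threshold with the same sign on both arrays, leaving out probes with several gene names. From each list it takes the 2 lowest and 2 highest members upstream and the lowest and highest coding member, and it adds 18 fixed loci, 16 of which were measured. For list members and fixed loci, regions shared by divergent genes were kept, so a region can count for both of its genes in list counts and tests. Examples of these genes are given in the text.

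The tests were tested on simulated data. For probes against 0 (41454 probes, 20 draws), a mean of 0.6% of simulated ratios of 0.25, 81.5% of 0.5, 98.1% of 1 and 99.8% of 2 were recovered. On average 6.06% of calls were false, from 2.19% to 11.2% between draws. For the difference per gene (5000 genes, 20 draws), 68.3% of changes of 0.25, 97.7% of 0.5, 99.5% of 1 and 100% of 2 were recovered, and 6.11% of calls were false, from 2.13% to 22.7%, so the mean lay slightly above the nominal 5%. Only a small share of features was changed in these simulations. In the data 19465 probes passed above 0 and 19499 below, which makes the adjusted threshold looser. The simulated rates of recovery and of false calls therefore do not carry over to these data. Camera gave a simulated shifted list among 5000 genes p = 3.82e-06 with the preset and p = 0.0929 with the estimated correlation. In 40 draws without an effect, the circular shift test gave p under 0.05 in 5% for upstream regions and 7.5% for tRNA stretches.

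Alternatives fixed with the lists were normexp background correction (offset 50) of the raw intensities, loess within arrays, quantile scaling between arrays, no filter on dim probes, a filter on dim and saturated probes of both channels, the deposited value table, each array alone, a threshold of 0.01, eBayes with trend and robust, an upstream window of 250 bp or the whole intergenic region, chromosome ends of 10 kb, bins of 50 bp and fry. Added after seeing the data were the uncentred table, random lists (also run with normexp, loess, quantile scaling, both filters and both windows), the highest upstream bin and tRNA stretches against other intergenic probes. Base composition, probes with several genome matches, centromeres, replication origins, transposons and ribosomal DNA were not analysed here, for lack of probe sequences or annotation.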

Results

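Nucleosomal DNA and genomic DNA of budding yeast (Saccharomyces cerevisiae) were compared across the genome on 2 arrays, replicate 1 and replicate 2, which form 1 group. The cells had been held in G1 with the mating pheromone alpha factor. Per the labels, the nucleosomal DNA, left after digestion of chromatin with micrococcal nuclease (an enzyme that cuts the linkers between nucleosomes), carried Cy5, and the genomic DNA, from sonicated chromatin, carried Cy3. Median raw spot brightness was 32997 and 33242 in Cy5 and 17885 and 16928 in Cy3, over local backgrounds of 80.5 and 80 in Cy5 and 59 and 57 in Cy3. Of the 41775 probes, 41454 were kept. All values below are log2 ratios of Cy5 over Cy3, with the median of each array set to 0, so that a value above 0 means more of the DNA labelled nucleosomal relative to a typical probe. Mitochondrial DNA, which is not packaged by histones, lay on the high side of this ratio together with the regions upstream of genes, so what the sign means for nucleosomes is left open here, and values are given as measured in the channels as labelled.

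The first question was where along the genome the ratio departed from the array median. The limma test (Benjamini-Hochberg adjusted p under 0.05) placed 19465 probes above 0 and 19499 below. The near-equal split follows from centring on the median, because uncentred values placed 16946 probes above and 22144 below. Across probes the ratios of replicates 1 and 2 correlated with Pearson's r = 0.998 and Spearman's rho = 0.997, and the difference between the arrays had an SD of 0.065. Probes are not independent replicates, so these coefficients carry no p-value. Both arrays lay on 1 slide and nothing in the labels says that they held DNA of separate cultures, so the limma p-values measure only the spread between these arrays, which may be technical. Permutation p-values are taken over positions or genes within these arrays and carry no spread between cultures. The number of arrays limits the precision.

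Regions upstream of genes stood above coding regions. Nuclear probes within 500 bp upstream of a start codon (6570 probes) had a median of 0.69, and 69.1% of them lay above 0. Coding probes (30056) had a median of -0.11, with 43.8% above 0. The difference was 0.80 ± 0.0056 (SD, n = 2 arrays), with 0.80 on replicate 1 and 0.79 on replicate 2. When values were rotated along the chromosomes under a fixed annotation, the two-sided permutation p was 0.0001, the smallest that 10000 rotations can give. An exact sign-flip test of 2 arrays cannot go below 0.5 and was not used.

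The measured difference was not of the same size in each kind of intergenic region. Intergenic regions between 2 start codons (divergent, 3356 probes) exceeded coding regions by 0.73 ± 0.016 (SD, n = 2 arrays). Those between an end and a start (tandem, 5817 probes) exceeded them by 0.64 ± 0.0035. Convergent regions, which lie between 2 gene ends and hold no promoter of either neighbour (1878 probes), exceeded coding regions by 0.31 ± 0.0089. Each class had a permutation p of 0.0001, the smallest possible. The differences between the 3 classes were not tested. The convergent difference depended on the processing, with 0.63 after normexp background correction and 0.16 after loess.

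**Figure D1:**
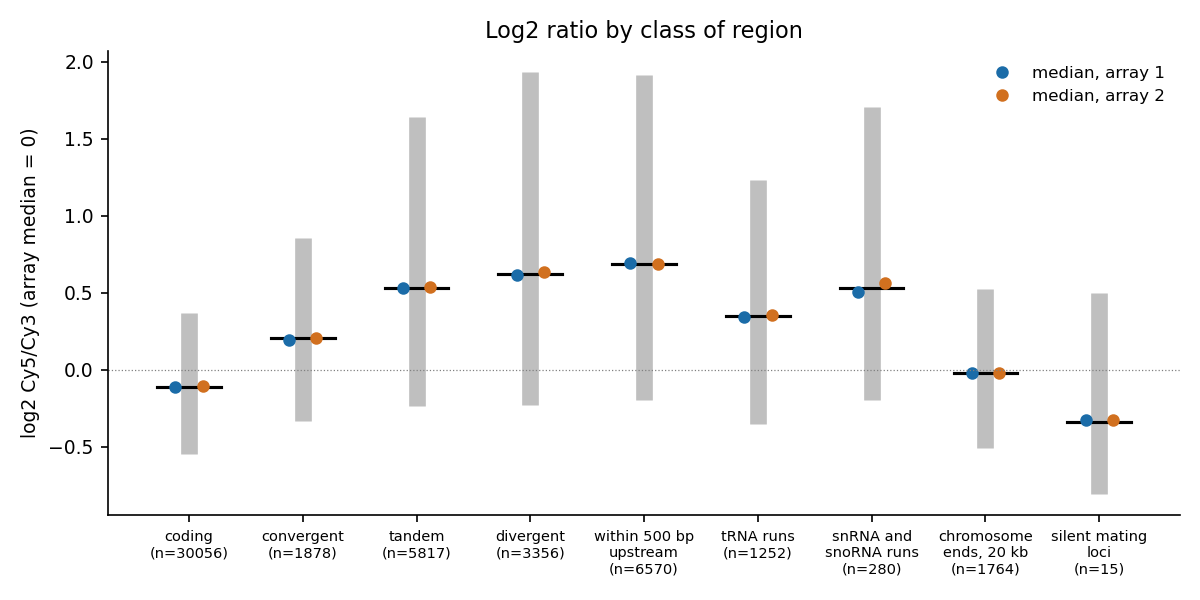
Log2 ratio of Cy5 over Cy3 (vertical axis, array median at 0) for coding regions, intergenic classes and special regions (horizontal axis, with the number of probes); grey bars span the quartiles, black lines mark the median of the mean values, and points mark the median on each array. Coding regions lie at -0.11, convergent, tandem and divergent regions at 0.20, 0.53 and 0.62, and the points of both arrays nearly coincide in each class.

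The ratio was also followed along genes, by distance to the start and stop codon. Bins on the intergenic side of either codon held only intergenic probes, and bins on the coding side only coding probes of that gene. A step at these boundaries therefore restates the difference between the classes and does not locate it. Between 100 and 200 bp upstream of the start codon the median was 0.77 ± 0.024 (3391 genes), the highest of the 100 bp bins upstream. Here and below in this profile, ± is the SE of the mean over pairs of probe and gene, set beside a median. A probe shared by divergent genes enters once for each, so these pairs are not independent. With bins of 50 bp the highest lay 250 to 300 bp upstream (0.83), so the place of the maximum depends on the bin width. Over the first 100 bp of the coding side it was -0.086 ± 0.029 (872 genes), and from 200 to 1000 bp into the gene the bins averaged -0.12. The highest upstream bin stood 0.89 above that coding level, and the bin planned for the contrast, the lowest upstream one (900 to 1000 bp away), still stood 0.51 above it. Only 339 genes had probes in that lowest bin, against 3391 at 100 to 200 bp, so it describes genes with long upstream regions. Past the stop codon the median rose from -0.052 ± 0.028 in the last 100 bp of the gene to 0.54 ± 0.044 at 200 to 300 bp, then declined to 0.24 ± 0.097 at 900 to 1000 bp. Bins past the stop codon hold every intergenic probe there, also those annotated upstream of the next gene. Tandem regions hold 5817 probes and convergent ones 1878, so the rise cannot be assigned to gene ends alone. Start and stop positions were placed midway between flanking probes, which stood 257 bp apart (median), so finer structure such as single nucleosomes was not resolved.

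**Figure D2:**
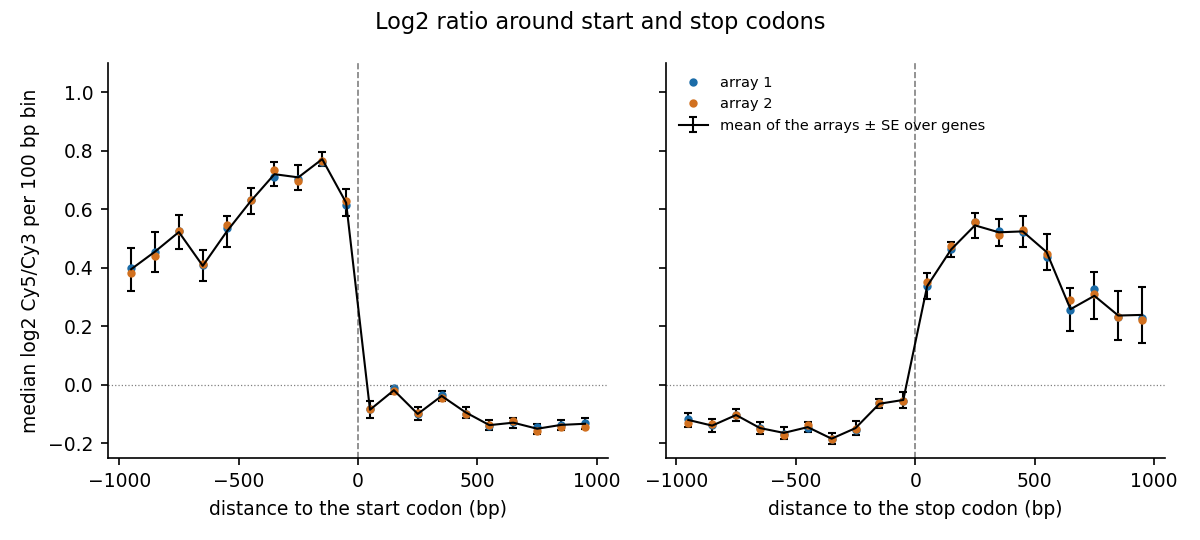
Median log2 ratio of Cy5 over Cy3 (vertical axis) in 100 bp bins against distance to the start codon (left) and stop codon (right) in bp. The line is the median of the mean of both arrays, and points are the arrays. Bars are the SE of the mean over pairs of probe and gene. The ratio drops from 0.77 upstream of the start to -0.086 within the gene and rises again to 0.54 past the stop. Bins on the coding side hold only coding probes and the other bins only intergenic ones. Bins past the stop also hold probes upstream of a next gene.

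Most genes showed the same difference one by one. Of 4997 genes with probes in both regions, 3738 had a higher upstream than coding value and 1060 a lower one (limma, adjusted p under 0.05), with a median difference of 0.96. Both arrays gave the same sign for 98.7% of genes, with 76.1% higher upstream on both and 22.6% lower on both. After normexp background correction 3290 genes were higher and 603 lower.

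Among the highest upstream values named by the rule were those of FAR1, the inhibitor of the cyclin-dependent kinase needed for arrest by pheromone, at 4.66 ± 0.023 (SD, n = 2 arrays; chromosome 10, 126220 to 126279), HMT1, a protein arginine methyltransferase, at 4.47 ± 0.080, and HCA4, an RNA helicase of ribosome assembly, at 4.39 ± 0.044. SED1, a cell wall glycoprotein, followed at 4.29 ± 0.050. UTP13, part of the complex that processes ribosomal RNA of the small subunit, stood at 4.25, NAM7, a helicase of nonsense-mediated decay, at 4.24, and POS5, a mitochondrial NADH kinase, at 4.23. The lowest upstream values were those of BUD21 at -2.43 ± 0.0079 (chromosome 15, 472689 to 472748), the DNA damage checkpoint gene DDC1 at -2.27 ± 0.014, the cell wall kinase gene BCK1 at -2.24 ± 0.10 and HRD1, a ubiquitin ligase of the endoplasmic reticulum, at -2.20 ± 0.047. The RNA helicase gene DBP2 stood at -2.06, TEP1 at -1.98, SGO1, a protector of centromeric cohesion, at -1.88, and UPS1 at -1.79. After normexp TEP1 turned to 0.89, BUD21 was -0.88 and UPS1 -1.13, and the highest values shrank by over 1.5 times for FAR1 (2.89), HCA4 (2.89), SED1 (2.79) and UTP13 (2.74). Each of the genes named here had 1 probe in the window. Adjusted p ranged from 1.09e-07 to 6.72e-07 (limma).

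Among the 8 highest coding values, YDL159W-A stood at 4.87 ± 0.012 (SD, n = 2 arrays; chromosome 4, 172247 to 172306), YLR406C-A at 4.22 ± 0.097 and YGR240C-A at 3.86 ± 0.058. YLR412C-A at 3.39, YBL044W at 3.28, UTR5 at 3.18 and MIN10 at 3.16 followed, each on 1 probe. The lowest coding values were those of YCR043C at -2.28 ± 0.012, RRS1, which acts in ribosome assembly, at -1.96 ± 0.028, RPA14, a subunit of RNA polymerase I, at -1.93 ± 0.014, TOS6 at -1.93 and GIM4, a subunit of the prefoldin chaperone, at -1.89. IMP3, a ribosome assembly factor, stood at -1.67 on 2 probes, YKL183C-A at -1.65 and YOL013W-B at -1.59. RPA14 and YOL013W-B turned above 0 after normexp, to 0.39 and 0.70, and RRS1 no longer passed (-0.0018, limma adjusted p = 0.991). Adjusted p ranged from 1.28e-13 to 5.65e-10 (limma).

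Loci with well studied promoters, or of interest in cells arrested by pheromone, were fixed beforehand, and 16 of 18 had upstream probes. HIS3 (histidine synthesis) was the highest at 2.94 ± 0.019 (SD, n = 2 arrays; chromosome 15, 721714 to 721771), followed by SUC2 (invertase) at 2.81 ± 0.032. Among genes of mating, STE2, the alpha factor receptor, stood at 2.36 ± 0.017, FUS1, which acts in cell fusion, at 2.31 ± 0.031 (chromosome 3, 71433 to 71720), BAR1, the protease that degrades alpha factor, at 1.02 ± 0.039, FIG1 at 0.76 ± 0.076 and STE6, the a-factor exporter, at 0.57 ± 0.024. The agglutinin gene AGA1 stood at 2.16, and its only probe was saturated in Cy5 on both arrays, which makes this a lower bound. CLN2, a G1 cyclin gene, stood at 1.73 ± 0.0079, the region shared by GAL1 and GAL10 at 1.53 ± 0.013, CHA1 (serine and threonine breakdown) at 1.45 ± 0.0029 and PHO5 (acid phosphatase) at 1.13 ± 0.0068 (chromosome 2, 430989 to 431048). RNR3 stood at 0.35 ± 0.0097 and ADH2 at 0.20 ± 0.0054. HO, the mating-type switching endonuclease gene, had 0.029 ± 0.025 and did not pass the test (limma, adjusted p = 0.214). With a window of 250 bp, CLN2, STE6, ADH2 and RNR3 turned below 0, to -0.24, -0.20, -0.11 and -0.11. HO passed at 0.69 with that window (limma, adjusted p = 4.98e-06), at 0.12 after loess and at -0.22 with the whole intergenic region. STE2 and SUC2 were 0.92 and 1.82 with 250 bp, and CLN2 and SUC2 were 0.97 and 1.05 with the whole region. After normexp STE6 and RNR3 no longer passed, and ADH2 and BAR1 were 0.75 and 1.56. After loess PHO5 was 0.63, BAR1 0.56, FIG1 0.42, RNR3 0.11 and ADH2 0.061. These values depend on the window and the processing.

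**Figure D3:**
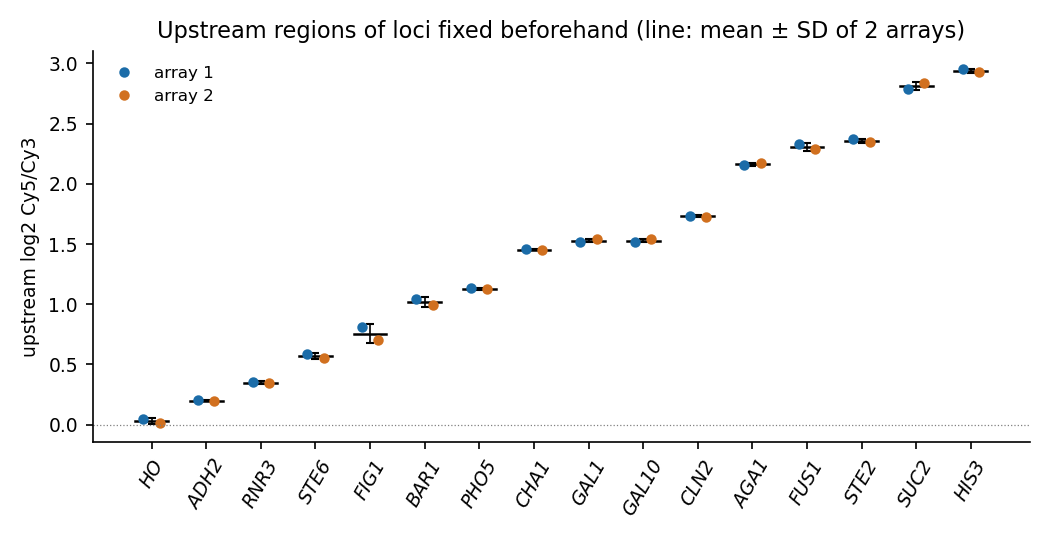
Upstream log2 ratio of Cy5 over Cy3 (vertical axis) of the 16 loci fixed beforehand that had probes, in rising order along the horizontal axis; points are the arrays and lines the mean ± SD of 2 arrays. HO lies at 0.029 and HIS3 at 2.94, and the arrays differ far less than the loci do.

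Special regions were compared with all other nuclear probes. Intergenic stretches that hold a tRNA gene (1252 probes) exceeded the rest by 0.36 ± 0.013 (SD, n = 2 arrays) and those that hold a small nuclear or nucleolar RNA gene (280 probes) by 0.54 ± 0.043, each with an adjusted permutation p of 0.0002, which comes from the smallest p possible. Most of the other nuclear probes are coding, so these calls do not set the stretches apart from other intergenic DNA. Small RNA stretches had a median of 0.53, beside 0.50 for intergenic probes outside tRNA stretches, a comparison that was not tested. Against other intergenic probes, a comparison chosen after seeing the data, stretches with a tRNA gene were 0.16 lower (difference -0.16, permutation p = 0.0001, the smallest possible), a call that ended after normexp (-0.070, permutation p = 0.0819). The 20 kb at the chromosome ends (1764 probes) differed from the rest by -0.015 (adjusted permutation p = 0.652). The silent mating loci (15 probes) differed by -0.33 (adjusted permutation p = 0.488). Normexp moved the silent loci to 0.81 (adjusted permutation p = 0.028), the ends to 0.012 and the tRNA stretches to 0.63, while loess moved the latter to 0.19.

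Mitochondrial DNA stood far above the nuclear genome. Its 222 kept probes exceeded nuclear probes by 4.51 ± 0.033 (SD, n = 2 arrays), with quartiles of 1.64 and 5.53, and 92.3% of them lay above 0. Medians of the 16 nuclear chromosomes ranged from -0.065 to 0.038. No rotation along a chromosome can test a whole chromosome, so this is a value without a test. Of the 292 mitochondrial probes with uniform spots, 70 were left out because Cy3 was not well above background, and 37.8% of those kept were saturated in Cy5 on both arrays. With dim and saturated probes of either channel left out the difference was 2.62.

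**Figure D4:**
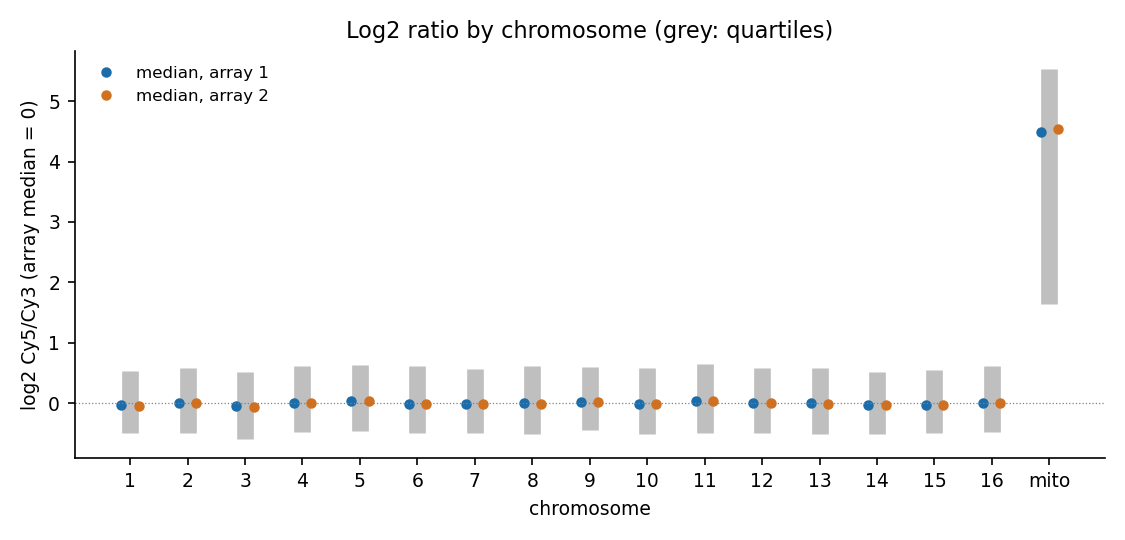
Log2 ratio of Cy5 over Cy3 (vertical axis, array median at 0) by chromosome (horizontal axis, 1 to 16 and mitochondrial DNA); grey bars span the quartiles and points are the medians of each array. The nuclear chromosomes lie between -0.065 and 0.038, and mitochondrial DNA lies at 4.50.

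Groups of genes were compared by 15 lists fixed beforehand, each for upstream and coding regions. Over all genes 69.1% of upstream probes and 43.8% of coding probes lay above 0, called or not. These are shares of probes and not of genes called. A high count of members above 0 upstream therefore does not by itself set a list apart. Camera and random lists, given below, compare the lists with other genes. Upstream of cytosolic ribosomal protein genes the median was 2.05, against 0.85 for other genes. Of 125 measured members, 109 passed the limma test above 0, 15 below and 1 did not pass, both over all genes and adjusted over the list alone. RPL8B (5.27 ± 0.045, SD, n = 2 arrays) and RPL40A (4.47 ± 0.082) were the highest, each in a region shared with a divergent neighbour, while RPS0B (-1.49 ± 0.12) and RPS22B (-1.35 ± 0.0031) were the lowest. With the whole upstream intergenic region RPS0B turned to 0.64, RPS22B no longer passed (-0.017) and RPL8B was 1.66. After normexp RPS0B no longer passed (-0.30), RPS22B was -0.63, and RPL8B and RPL40A were 3.29 and 2.87. Their coding regions had a median of 0.11, against -0.085 for other genes, with 73 above and 46 below of 128, from RPL4B at 1.64 to RPS22B at -1.40, which turned to 1.27 after normexp. After loess the coding median of the list was -0.034, with 51 above and 63 below. Upstream of mitochondrial ribosomal protein genes the median was 1.39 (43 of 56 above, 11 below), with MRP20 at 4.14 and MRPL50 at -1.44. Upstream of glycolysis and fermentation genes the median was 1.80, and 18 of 18 passed above 0, from PFK2 at 0.16 to FBA1, the aldolase gene, at 2.75. PFK2 no longer passed after normexp (0.29) and was 0.96 with dim and saturated probes left out and 1.05 with the whole region. With a window of 250 bp it turned to -0.65, and the median of the list was 0.78, against 0.71 for other genes (permutation p = 0.902).

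Genes of the pheromone response and of a-cell identity had an upstream median of 1.36, with 24 of 26 above 0 and 1 below, among them FAR1 and the mating kinase gene FUS3 at 3.12 ± 0.025 (SD, n = 2 arrays). Histone genes had an upstream median of 1.32 (5 of 6 above, 1 below), with HHO1, the linker histone gene, at 3.02. Phosphate response genes stood at 1.08 (11 of 14 above, 3 below) with the polyphosphate synthesis gene VTC1 at 3.38 and the phosphate transporter gene PHO84 at 2.69. G2/M genes stood at 1.01 (11 of 18 above, 5 below) with CDC20 at 2.95, ribosome biogenesis genes at 1.01 (49 of 67 above, 16 below) with DBP10 at -2.06, proteasome genes at 0.85 (25 of 34 above, 9 below) with RPN10 at 2.96, and chaperone and heat shock genes at 0.85 (14 of 20 above, 5 below) with HSP150 at 3.34. Genes of RNA polymerase II and general factors stood at 0.78 (19 of 29 above, 10 below) with TAF5 at -1.11 (after normexp -0.063, no longer passing), and G1/S genes at 0.60 (25 of 33 above, 7 below) with the cyclin gene PCL2 at 4.20. Genes of meiosis and sporulation, which are off in vegetative cells, had an upstream median of 0.46 (29 of 40 above, 7 below), subtelomeric families 0.19 (6 of 12 above, 4 below) and genes of galactose use -0.045 (2 of 5 above, 1 below), with the galactose permease gene GAL2 at -1.51. The 2 galactose genes above 0, GAL1 and GAL10, share a divergent region and the same 2 probes. With a window of 250 bp the medians were 0.26 for phosphate response, 0.53 for G2/M, 0.52 for chaperone, 0.28 for meiosis, 0.047 for subtelomeric, 2.01 for histone (4 genes) and 0.76 for galactose genes, the last with a turned sign. Galactose genes also turned to 0.45 after normexp, which moved G1/S genes to 0.94, and were at -0.22 after loess. Subtelomeric families stood at 0.29 with dim and saturated probes left out. The whole intergenic region gave 0.68 for phosphate response, 1.44 for FUS3, 1.01 for HHO1, 1.72 for PHO84 and 1.77 for PCL2. CDC20 was 1.43 with 250 bp, and PCL2 and GAL2 were 2.70 and -0.93 after normexp. Counts adjusted over each list alone were identical for both regions in all 15 lists.

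Coding regions of the meiosis and sporulation list had a median of 0.17, with 26 of 43 above 0 and 16 below and SAE3, a meiotic recombination gene, at 2.02 ± 0.014 (SD, n = 2 arrays). The median was 0.062 after normexp and 0.0060 after loess. Coding medians below 0 that changed little were those of RNA polymerase II and general factors (-0.18), ribosome biogenesis (-0.14) and mitochondrial ribosomal proteins (-0.13). The other 10 lists lay between -0.23 (phosphate response) and 0.083 (glycolysis), and each moved by over 1.5 times or turned in an alternative. Galactose and histone genes turned from 0.016 and 0.021 to -0.12 and -0.016 after normexp, pheromone response genes from 0.023 to -0.098 after loess, and subtelomeric families from 0.047 to -0.051 with dim and saturated probes left out. Without a turn of sign, normexp gave -0.38 for phosphate response, -0.25 for G2/M, -0.20 for proteasome, -0.074 for G1/S and -0.061 for chaperone genes, and loess gave 0.22 for glycolysis.

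Camera, a test of each list against other genes, gave 0 of 30 calls at an adjusted p under 0.05, with 6 at an unadjusted p under 0.05. The lowest adjusted p was 0.0644 (upstream and coding regions of cytosolic ribosomal proteins and coding regions of meiosis genes), and with an estimated correlation it was 0.921. Against 10000 random gene lists of the same size, an alternative chosen after seeing the data, 3 of 30 list medians stood apart: cytosolic ribosomal proteins upstream (adjusted permutation p = 0.003) and coding (0.003) and meiosis genes coding (0.006). Only the upstream result held in every alternative it was run in. Both coding results ended after loess (adjusted permutation p = 0.363 for each), and that of meiosis genes also after normexp (0.078). Fry, which tests whether a list departs from 0 and not from other genes, gave 25 calls.

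**Figure D5:**
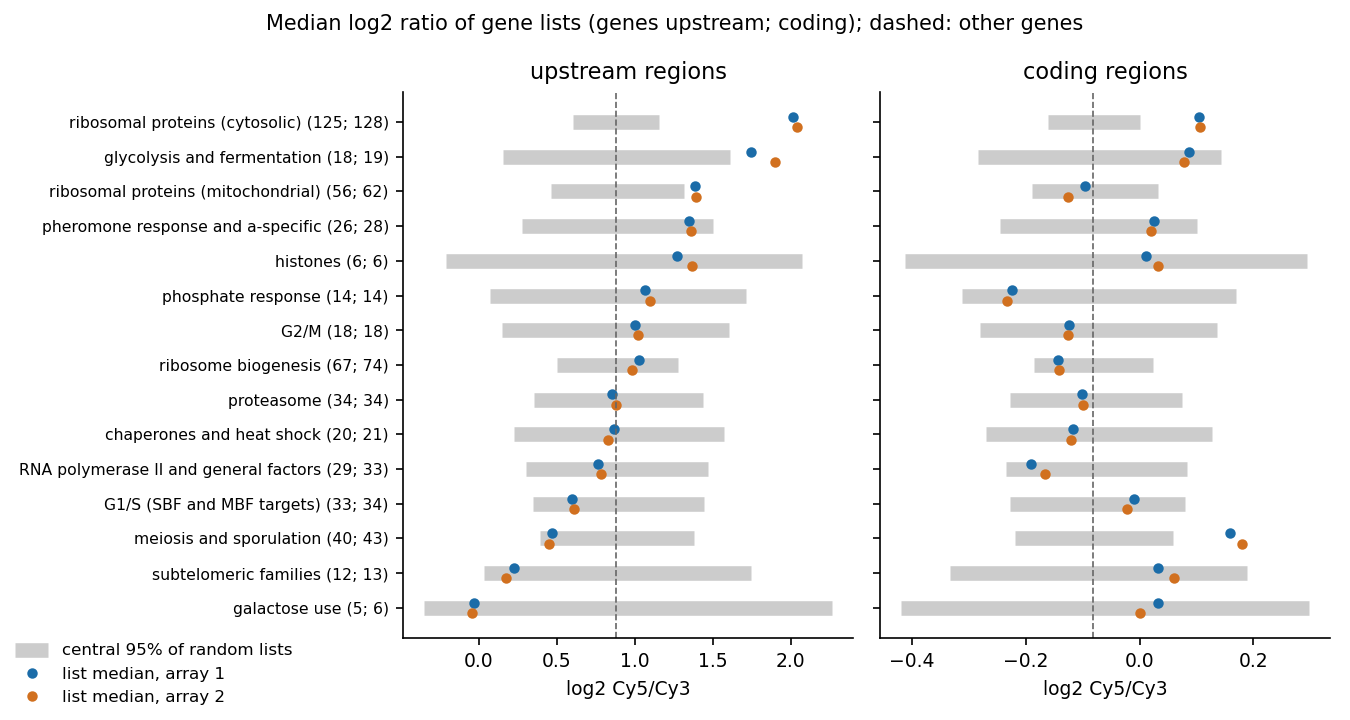
Median log2 ratio of Cy5 over Cy3 (horizontal axes) of the 15 gene lists (vertical axis, with the number of genes measured upstream and in coding regions) for upstream (left) and coding (right) regions; points are the arrays, grey bars the central 95% of medians of random lists of the same size, and dashed lines the median of other genes. Cytosolic ribosomal proteins lie outside the grey bars in both panels, at 2.05 and 0.11.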

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

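Every alternative was planned in advance except random lists, the uncentred table, the highest upstream bin and the comparison of tRNA stretches with other intergenic probes. Upstream minus coding stayed positive and past its test under every alternative run, from 0.60 (loess) to 0.99 (normexp), as did the divergent (0.54 to 0.91), tandem (0.46 to 0.87) and convergent (0.16 to 0.63) classes, tRNA stretches (0.19 to 0.63) and small RNA stretches (0.40 to 0.64). Both kinds of stretches are intergenic and were set here against all other nuclear probes, most of them coding. Counts of probes stayed within 1.5 times the planned ones. The deposited table, once centred, equals the planned values by construction and tests nothing. No paired analysis was possible because there is 1 group. Not run were base composition and probes with several genome matches, for lack of probe sequences, and counts of calls or list tests on an array alone, which leaves no residual degrees of freedom. The causes of the changes below were not tested.

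After normexp r between arrays was 0.927, genes lower upstream numbered 603 against 1060, the median difference per gene was 0.98, the mitochondrial difference 3.39, the lowest and highest upstream bins stood 0.67 and 1.05 above the coding side, and 1 list passed camera (cytosolic ribosomal proteins coding, adjusted p = 0.0201, but 0.997 with an estimated correlation). It turned the chromosome ends to 0.012 and the silent loci to 0.81, and tRNA stretches against other intergenic probes weakened to -0.070 (permutation p = 0.0819). Loess gave 0.79 per gene, 4.09 for mitochondrial DNA, and 0.40 and 0.67 for the bins. With dim and saturated probes left out the median per gene was 0.95 and mitochondrial DNA 2.62; with no background filter mitochondrial DNA was 4.03 and the lowest bin 0.50. Bins of 50 bp gave 0.41 and 0.95. Windows of 250 bp and of the whole intergenic region gave 0.81 and 0.92 per gene. The whole region let 2 lists pass camera (cytosolic ribosomal proteins, upstream and coding, adjusted p = 0.00921 and 0.0461, but 0.882 with an estimated correlation). With the uncentred table the same regions and meiosis genes coding passed (adjusted p = 0.0215, but 0.922 with an estimated correlation). Since camera with an estimated correlation missed a simulated shifted list, its high p-values do not decide about these calls. In place of camera, fry called 25 and random lists 3. Random lists called 2 after normexp, 2 after loess and 5 with the whole region: meiosis genes coding weakened to a list-minus-others median of 0.20 after normexp (adjusted permutation p = 0.078) and 0.11 after loess (0.363), and cytosolic ribosomal proteins coding to 0.076 after loess (0.363). New calls were glycolysis coding after loess (0.048), and mitochondrial ribosomal proteins upstream (0.0105) and subtelomeric families upstream (0.024) with the whole region. The subtelomeric list then held 35 genes, against 12 within 500 bp, so that call rests on a larger set of genes. Each array alone gave 0.95 to 0.96 per gene, 4.50 to 4.55 for mitochondrial DNA, 0.50 to 0.51 for the lowest bin and 0.87 to 0.88 for the highest.

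Of gene lists, none of which passed camera before, the mean of the list minus that of other genes changed sign for G1/S coding (-0.0077), G1/S upstream (-0.036), galactose use coding (-0.076) and proteasome upstream (-0.059) after normexp. It did so for G1/S upstream (-0.17) and phosphate response upstream (-0.099) with 250 bp, for G2/M (0.038), RNA polymerase II and general factors (0.036), histones (-0.050), phosphate response (-0.013) and proteasome (-0.0079), all upstream, with the whole region, and for proteasome upstream without the background filter (-0.00077) and with the strict one (-0.011).

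Of named genes, 15 changed sign after normexp: GAL10 coding (-0.092), KAR4 coding (0.34), MRPL28 coding (0.22), RPA14 coding (0.39), RPS22B coding (1.27), YOL013W-B coding (0.70), and upstream GAL7 (0.45), HHT2 (0.72), HO (-0.10), PHM6 (0.24), PHO8 (0.88), PRM10 (0.63), PRM8 (0.65), SPT15 (0.15) and TEP1 (0.89). Loess turned HHT2 coding (0.23) and HTB2 upstream (-0.15), and the strict filter STE6 upstream (-0.20). With 250 bp ADH2 (-0.11), CLN2 (-0.24), HTB2 (-0.055), PFK2 (-0.65), RNR3 (-0.11) and STE6 (-0.20) turned, and with the whole region COS9 (0.030), HO (-0.22), PHM6 (0.67), POL2 (0.30), PRM10 (0.16), PRM8 (0.21) and RPS0B (0.64). After normexp 9 kept their sign but no longer passed (limma): KIP2 coding (0.023), RRS1 coding (-0.0018), and upstream AAD3 (-0.31), GLK1 (0.41), PFK2 (0.29), RNR3 (0.33), RPS0B (-0.30), STE6 (0.41) and TAF5 (-0.063). So did RPS22B upstream (-0.017) with the whole region. Upstream GAL7 (-0.24), HO (0.12) and PRM8 (-0.50) newly passed after loess, and GAL7 (-0.38) and HO (0.69) with 250 bp. Quantile scaling and no filter changed the sign or call of 0 named genes.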

Other observations

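Tests chosen or known in outcome only after the result was seen were those of the Cy3 signal of mitochondrial probes, of loess, of mitochondrial carry-over, of the meiosis list and of ribosomal protein genes.

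Upstream regions of genes lying lower than their coding regions were found in most lists. By the limma test 1060 of all 4997 genes had a lower upstream value. In the lists these were 5 of 11 subtelomeric genes, 9 of 29 genes of RNA polymerase II and general factors, 10 of 40 meiosis, 14 of 67 ribosome biogenesis, 7 of 34 proteasome and 14 of 125 cytosolic ribosomal protein genes, and 0 of 18 glycolysis and 0 of 6 histone genes. The difference between lists in these shares was not tested.

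The ratio of the channel labelled nucleosomal over the channel labelled genomic was highest where histones are absent (mitochondrial DNA) and upstream of genes. A dye bias that follows the mean intensity of both dyes is argued against as the whole cause. Loess removes only the average trend with that intensity, and the upstream-minus-coding difference was 0.60 (log2) after it, beside 0.80 before. A bound of 0.3 for this difference was set only after the result was seen, so passing it decides nothing. Cross-hybridising mitochondrial DNA stays open: the difference was 0.57 among the dimmest of 4 groups by Cy5 signal, above the bound set beforehand, but that bound was wrong because the groups were formed on the numerator of the ratio, so neither this value nor a trend across the groups decides. A candidate explanation is that the dyes were exchanged relative to the labels: upstream probes differed from coding probes by -1.02 (log2) in Cy3 and by -0.020 in Cy5, as a nucleosomal sample in Cy3 would give, but brightness also depends on probe affinity, and base composition was not analysed here. For mitochondrial probes exchanged dyes cannot be told apart from mitochondrial DNA carried through the nuclease preparation. The nuclear difference of 0.80 does not bear on such carry-over. Exchanged dyes were predicted to put mitochondrial Cy3 below and Cy5 above nuclear probes. The kept probes show this (-4.15 and 0.61). All probes with uniform spots do not (-4.58 and -0.53), and the kept ones were chosen by Cy3 brightness. Dyes as labelled were predicted to put mitochondrial Cy3 above nuclear Cy3, which failed in both sets of probes. The high mitochondrial ratio thus came mostly from low Cy3, with Cy5 nearer to that of nuclear probes. Since probe affinity also sets brightness, and can lower both dyes of a probe, neither these values nor the failed predictions decide between the causes. No biological explanation was tested.

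Genes of cytosolic ribosomal proteins had a median upstream-minus-coding difference of 1.98, above the central 95% of random lists (upper end 1.25; adjusted permutation p = 0.003; 108 of 125 genes higher). A dye bias that follows the mean intensity of both dyes is argued against as the whole cause here. The list exceeded other genes by 0.89 after loess (permutation p = 0.0002, the smallest possible), which removes only the average trend with that intensity. This excess was 1.03 before loess and 0.67 after normexp. Genes of meiosis and sporulation had 0.39, below the central 95% of random lists (lower end 0.44), but this did not pass adjustment over the 15 lists (adjusted permutation p = 0.215). Unadjusted, its permutation p was 0.0286, 0.0108 with dim and saturated probes left out, 0.1 after normexp and 0.211 after loess, so whether genes that are silent in these cells differ less stays open. Transcription was not measured here, and a link of the ribosomal protein pattern to it is an untested hypothesis, which may be looked at with expression data.

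Many ribosomal protein genes have an A and a B copy with nearly identical coding sequence, so cross-hybridisation could make their coding values alike. Coding values differed by a median of 0.37 within 53 pairs, against 0.42 in permuted pairs (one-sided permutation p = 0.201), and upstream values by 1.12 within 51 pairs, against 1.35 (p = 0.123, permutation). The pairs were slightly closer than permuted ones in both regions without passing the test, and a p that misses the threshold excludes nothing, although the prediction had counted it against this cause, so cross-hybridisation between copies stays open.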
